A study of Caenorhabditis elegans with 6 samples.

How the data were processed

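Polyadenylated RNA of adult Caenorhabditis elegans was measured by RNA sequencing in 3 wild type (N2) and 3 linc-4 deletion libraries, and the deposited table holds all 6. Per the submitters' processing notes, cutadapt 2.10, TopHat2 2.1.1, HTSeq 0.12.4 and DESeq2 1.22.2 were used by the authors with the genome build WBcel235; their settings, the strandedness of the counting and its handling of reads shared between genes are not given in the sources used here. Without known strand, reads of overlapping or antisense genes cannot be told apart. Per the labels, RNA was extracted with TRIzol and a column kit, and enriched for mRNA before fragmentation and reverse transcription.

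The authors' deposited table holds, per gene, a raw read count for each library, the same count divided by 1 size factor per library, and their own comparison with a log2 fold change, its standard error, a score (the Wald statistic), a p-value and an adjusted p-value. Of 46904 rows, 22389 carry a raw count and 24515 carry a question mark in place of it; the size-factor-normalized columns carry 17553 numbers. The question mark was read as no value. Values were whole numbers of at least 0 in every row that carried a raw count. No read count column could be registered under its accurate unit, counts, because the format check used for this work reads the question mark as text, so these columns were registered without a unit and their ranges were tested separately on the values.

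The test planned before the data were examined was the edgeR quasi-likelihood test, and it was not used for any value reported here, because that check admits it only for columns registered as counts. limma-voom, planned as an alternative, took its place; this was decided after both had been run once and the number of genes each called had been seen. Other choices of the design were kept. The counts as the authors deposited them were tested with limma 3.58.1 in R 4.3.3. Genes were kept with at least the CPM that 10 reads make at the median library size in 3 libraries and at least 15 reads in all, which left 13778 genes and between 99.7% and 99.8% of the reads of each library. Scaling factors were trimmed means of M values (30% of log ratios and 5% of abundances trimmed), written out in a script. Fold changes are linc-4 over wild type, two-sided, and Benjamini-Hochberg adjusted p under 0.05 was the threshold, with no minimum fold. CPM values use these factors and are given as mean ± SD of 3 libraries.

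Total counts ran from 3736372 to 12790323. A floor of 3 reads stood for 0.771 CPM in wild type 1, the shallowest library, and for 0.228 CPM in linc-4 3, the deepest. Where a named gene had under 10 reads summed over a group, the ratio of summed reads is given with an exact 95% binomial interval; intervals and floors cover counting error only. Pairs of libraries of 1 group differed by more than counting noise, with a chi-square per degree of freedom from 5.31 to 23.4, so no pair was treated as repeated deposits of 1 library. The labels do not say that libraries came from separate cultures, and p-values then measure only the spread between these libraries.

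Gene lists, 33 in number, were fixed before the data were examined, and 32 had at least 5 tested members; the list of ribosomal RNA had 1 tested member, with a log2 fold change of 0.50, and no list test. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and counts of calls were also adjusted over the list alone. Some genes are in more than 1 list. The list named for replication-dependent histones takes every his gene and so holds his-24, a linker histone, and his-70, a variant. The 5 tested genes on each side of linc-4 were taken as its neighbours. Positions are those of the deposited table (WBcel235), and exons are from Ensembl release 115 of the same build. The rule for named genes was also fixed before: linc-4; the 12 highest and 12 lowest log2 fold changes among genes past the threshold with a mean count of at least 50 and no overlap between groups; up to 4 members with the smallest p of each list that passed camera or held at least 3 calls; called members of the DBL-1 list; called neighbours; and called lincRNAs.

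Alternatives were median-of-ratios and upper-quartile scaling, no filter on low counts, a mean count of at least 10, a replicate block, leaving out each library, a log2 fold change of at least 1, a test against 0.5, the removal of sperm protein, vitellogenin and collagen genes, an estimated correlation, fry, lists of at least 3, and 10 neighbours on each side. Limma-trend on log2(CPM + 1) and the authors' deposited table were added after seeing the data. Terms of the gene ontology column of the deposited table were tested with a hypergeometric test among tested genes with a term, for terms of 10 to 500 genes.

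The fit was tested on simulated counts for this comparison, drawn for 13778 genes from the mean share of each gene and the real library sizes with a dispersion of 0.025. Of 50 genes changed at each size, 12% were recovered at 1.5-fold, 60% at 2-fold, 98% at 4-fold and 96% at 8-fold, with 2 unchanged genes called. A list of 40 genes raised 1.5-fold was recovered, and 0 of 20 unchanged lists were called. Simulated genes varied independently of each other, so this could not test camera on lists whose genes vary together. The simulation changed 200 genes, fewer than were called in the data, so rates of recovery may differ there.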

Results

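Polyadenylated RNA was sequenced from adult Caenorhabditis elegans grown on solid medium. The 6 libraries fall into 2 groups of 3: N2, the laboratory wild type, and a CRISPR deletion of linc-4 in the N2 background. linc-4 is annotated as a long intergenic non-coding RNA (lincRNA), a transcript from between protein-coding genes that encodes no known protein. The series names lincRNAs of the germline and the growth of somatic tissue as its subject. Total gene counts were 3736372, 7428665 and 5643577 in wild type 1 to 3 and 7567425, 6560089 and 12790323 in linc-4 1 to 3. Of 22389 genes with counts, 13778 were tested. The first principal component held 56.7% of the variance and separated the groups.

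The deleted gene was nearly absent from the mutant libraries. linc-4 (WBGene00219306) lies on the + strand of chromosome II from 6268939 to 6269516 (WBcel235) and has 2 exons, from 6268939 to 6269008 and from 6269371 to 6269516. The wild type libraries held 193, 345 and 234 reads of linc-4, and the linc-4 libraries held 5, 1 and 1. The level was 48.1 ± 5.32 CPM (counts scaled to library size; SD, n = 3) in wild type and 0.288 ± 0.307 CPM (SD, n = 3) in the mutant. By summed reads, 772 against 7, wild type was 191 times higher after scaling for depth, with a 95% counting interval of 92.1 to 476. The limma-voom log2 fold change was -7.52 (SE 0.48, adjusted p = 1.9e-06). The extent of the deletion is not given in the sources used here, so the few remaining reads cannot be placed inside or outside it.

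Next to linc-4, the gene F13H8.8 was 15.2-fold higher in the mutant. F13H8.8 (WBGene00017441) is protein-coding, lies on the opposite strand from 6265612 to 6268083, and its annotated start is 856 bp from that of linc-4. It rose from 2.48 ± 1.02 to 38.7 ± 4.82 CPM (SD, n = 3 each; log2 fold change 3.92, SE 0.29, adjusted p = 2.9e-06 by limma-voom over all genes). Further along the same side, F13H8.12 rose 2.07-fold (adjusted p = 0.0083) and nmgp-1 rose 1.70-fold (adjusted p = 0.038). These last genes lie on 1 strand and overlap by 3 bp, so a few of their reads may be shared. The nmgp-1 call over all genes was lost when any library other than wild type 2 was left out, with an adjusted p up to 0.14 without wild type 3. F13H8.3, between them and F13H8.8, had a log2 fold change of -0.41 and did not pass. On the other side, F13H8.2 starts 854 bp from the end of linc-4 and had a log2 fold change of -0.22 (SE 0.18), and none of the 5 genes there passed. Adjusted over the list alone, 3 of the 10 nearest tested genes passed, and 2 of 10 passed without wild type 1, without wild type 3 or without linc-4 2.

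**Figure D1:**
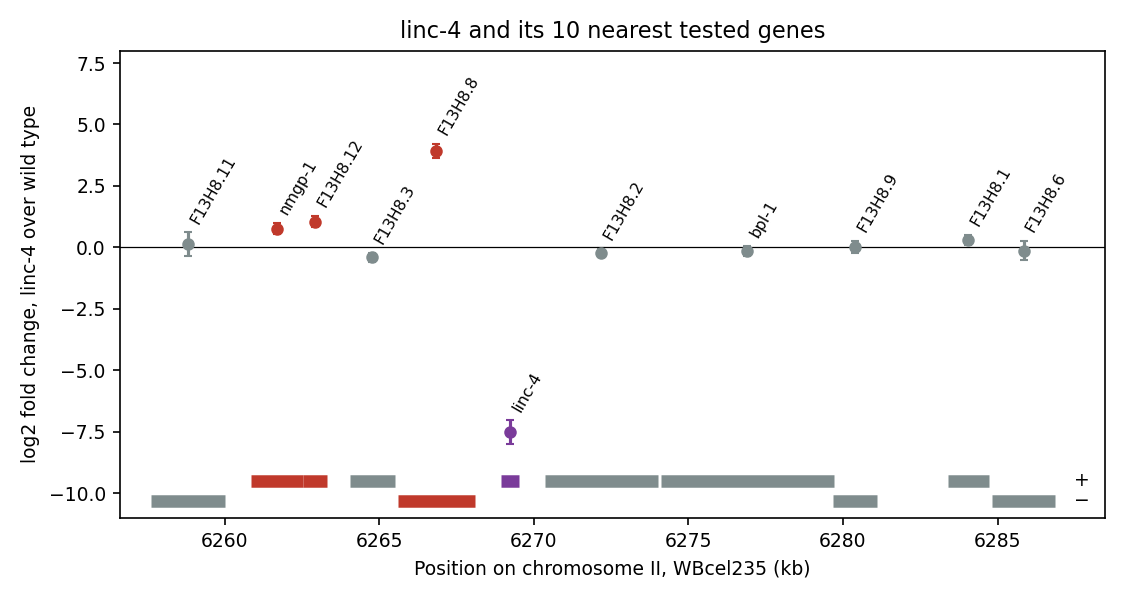
Log2 fold change of linc-4 over wild type (y axis; bars, standard error; 3 libraries per group) for linc-4 and its 10 nearest tested genes, at each gene's midpoint on chromosome II (x axis, kb). Bars at the bottom show the gene spans by strand, with linc-4 in purple, genes that passed adjusted over the 10 neighbours in red and the others in grey; F13H8.8 stands at 3.92 and linc-4 at -7.52.

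Across the transcriptome, acs-2, an acyl-CoA synthetase of mitochondrial fatty acid oxidation, rose from 7.91 ± 1.48 to 120 ± 14.6 CPM (SD, n = 3 each), and acdh-1, a short-chain acyl-CoA dehydrogenase, fell from 293 ± 16.6 to 44.5 ± 1.45 CPM. Their log2 fold changes were 3.91 (SE 0.20) and -2.72 (SE 0.13), each with adjusted p = 2.1e-07. Among the 13778 tested genes, the largest fitted rise was that of F57A10.4, with 1 read in all wild type libraries and 667 in the mutant ones, a ratio of 386 with a 95% counting interval of 69.0 to 15254. F56A4.3 had 4 wild type reads and 454 mutant reads, a ratio of 65.6 with an interval of 25.5 to 242. Y53G8AM.5 rose 64.9-fold, from 1.18 ± 0.844 to 78.4 ± 14.6 CPM. The ABC transporter gene haf-3 rose 18.9-fold, ZK218.5 rose 19.3-fold, F07C4.12 rose 15.6-fold and F49F1.7 rose 12.2-fold. The C-type lectin gene clec-60 rose 10.9-fold, the acyltransferase homologue oac-20 rose 10.2-fold and T22F3.11 rose 8.64-fold. Falls were smaller. After linc-4, the largest fitted fall among the tested genes was that of B0205.14, which fell 11.5-fold, from 17.1 ± 2.32 to 1.42 ± 0.557 CPM. Its neighbour B0205.13 fell 3.41-fold. The cuticle collagen genes col-74 and col-165 fell 5.09-fold and 4.30-fold, and folt-2, of the folate transporter family, fell 3.86-fold. Y47D3B.4, Y75B7B.2, T05E12.6, Y48E1B.8 and the ABC transporter gene pmp-5 fell 3.81-fold, 3.71-fold, 3.54-fold, 3.40-fold and 3.13-fold. acdh-1 overlaps C55B7.3 and col-74 overlaps ZK1248.13, so part of their reads may belong to those genes. F57A10.4, Y47D3B.4 and pmp-5 each overlap 1 annotated gene that was not tested, and haf-3 overlaps 2. These 24 genes, linc-4 and F13H8.8 among them, were chosen by fold change among called genes with a mean count of at least 50 whose 3 values in 1 group did not overlap the 3 of the other, so genes with fewer reads are not ranked with them.

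In total 1591 genes were higher and 989 lower in the mutant by limma-voom at an adjusted p under 0.05, or 18.7% of those tested. At least 2-fold changes were mostly rises, 805 against 89, as were those of at least 4-fold, 100 against 10. With upper-quartile scaling, which moved the median gene by 0.11 on the log2 scale, the split was 2065 higher and 476 lower. The total of 2580 calls fell to 947 without linc-4 2 (758 higher and 189 lower), 1136 without wild type 1, 1501 without wild type 3 and 1715 without linc-4 1.

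**Figure D2:**
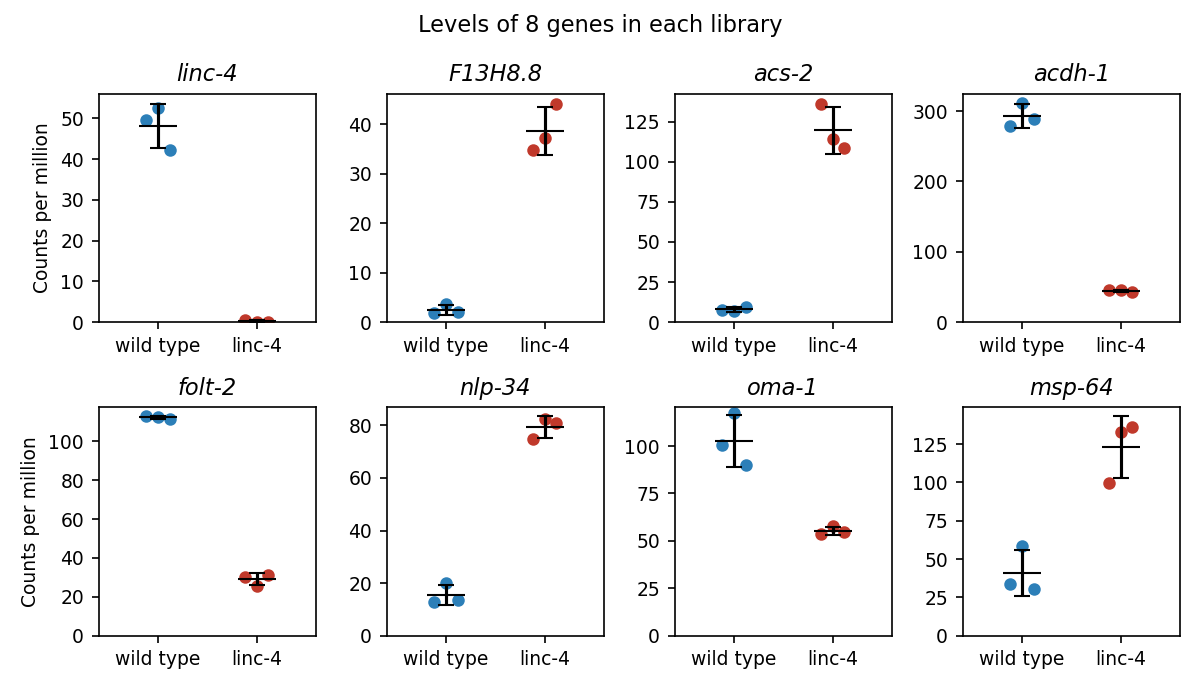
Level in CPM (y axis, linear from 0) of 8 genes in each of the 3 wild type libraries (blue) and the 3 linc-4 libraries (red), with the group mean (line) and SD (bars). linc-4, acdh-1, folt-2 and oma-1 are lower in every mutant library than in any wild type library, and F13H8.8, acs-2, nlp-34 and msp-64 are higher.

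Of 27 tested oocyte and eggshell genes, 21 fell and none rose (23 adjusted over the list alone), with a median log2 fold change of -0.60. They included mex-5 and mex-6, RNA-binding proteins of oocyte and embryo polarity, which fell 2.02-fold and 1.75-fold. oma-1, needed for oocyte maturation, fell from 103 ± 13.8 to 55.2 ± 2.18 CPM (SD, n = 3 each; adjusted p = 0.0017), and the eggshell gene cbd-1 fell 1.68-fold. Among 37 mitotic and meiotic germline genes 11 fell and none rose (17 adjusted over the list alone). The P granule genes pgl-3 and glh-1 fell 1.74-fold and 1.59-fold, gld-3 fell 1.57-fold and the meiotic chromosome axis gene htp-2 fell 1.57-fold; the calls of glh-1 and htp-2 were lost without linc-4 2 (adjusted p = 0.062 and 0.055). Among 34 small RNA pathway genes 3 fell (2 adjusted over the list alone), with a median of -0.38: hrde-1, a nuclear Argonaute of the germline, fell 1.90-fold, rde-11 fell 1.76-fold and sid-1 fell 1.45-fold. The sid-1 call was lost when any library was left out, with an adjusted p up to 0.11 without linc-4 1. Of 29 zygotic embryo genes 8 fell and 1 rose (10 and 2 adjusted over the list alone), and sdz-18, sdz-19, sdz-30 and vet-2 fell 4.27-fold, 3.08-fold, 2.31-fold and 1.90-fold. Of the 6 vitellogenin genes, which encode yolk proteins made in the intestine, 4 fell (5 adjusted over the list alone): vit-4 fell 1.64-fold, vit-6 fell 1.57-fold, vit-1 fell 1.42-fold and vit-2 fell 1.39-fold. The vit-2 call was lost when any library was left out. Those of vit-1 and vit-6 were lost in 4 and 3 of 6 fits with 1 library left out. Without linc-4 2 the adjusted p was 0.071 for vit-6, 0.13 for vit-1 and 0.16 for vit-2. camera, with a preset correlation between genes, gave adjusted p = 5.2e-12 for oocyte and eggshell genes, 1.2e-07 for germline genes, 1.9e-05 for small RNA genes, 0.00083 for zygotic genes and 0.0013 for vitellogenins. With an estimated correlation the adjusted p was 0.089 for the first 4 of these lists and 0.19 for vitellogenins.

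Of 31 tested major sperm protein genes 16 rose and none fell (20 adjusted over the list alone), with a median log2 fold change of 0.75. msp-64 rose from 40.9 ± 15.2 to 123 ± 20.2 CPM (SD, n = 3 each; adjusted p = 0.00049), and msp-36, msp-31 and msp-49 rose 2.49-fold, 2.12-fold and 1.88-fold. Copies of this family are nearly identical, so the values of its members are uncertain, and msp-31 also overlaps aagr-2. Of 41 other sperm genes 23 rose and none fell (26 adjusted over the list alone), with a median of 0.74. nspd-10, spe-11, ssp-35 and nspd-1 rose 2.48-fold, 2.23-fold, 2.02-fold and 1.97-fold. camera gave adjusted p = 4.0e-09 for each list, and the adjusted p was 0.29 and 0.15 with an estimated correlation. The major sperm protein list did not pass fry (adjusted p = 0.064).

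Of 36 tested epidermal antimicrobial peptide genes 29 rose and none fell (33 adjusted over the list alone), with a median log2 fold change of 0.98. nlp-34 rose from 15.5 ± 3.87 to 79.4 ± 4.05 CPM and nlp-25 from 34.1 ± 5.44 to 161 ± 22.8 CPM (SD, n = 3 each), while cnc-4 rose 4.67-fold and fipr-11 rose 2.88-fold. Of 45 lysozyme, saposin and infection response genes 14 rose and 1 fell (15 and 1 adjusted over the list alone): irg-4 rose 4.41-fold, lys-3 rose 4.23-fold, spp-2 rose 2.73-fold and dod-24 rose 2.59-fold. Of 92 C-type lectin genes 17 rose and 2 fell (19 and 2 adjusted over the list alone), and after clec-60 the examples are clec-218, which rose 2.99-fold, and clec-190, which rose 2.28-fold. camera gave adjusted p = 2.3e-19, 0.00083 and 0.018 for these lists, and the adjusted p was 0.089, 0.29 and 0.51 with an estimated correlation. The C-type lectin call was lost without wild type 1 (adjusted p = 0.093) and without the low-count filter (adjusted p = 0.16), and the list did not pass fry (adjusted p = 0.070).

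Of 18 tested targets of DAF-16, the insulin-regulated transcription factor, 9 rose and 1 fell (10 and 1 adjusted over the list alone), with a median log2 fold change of 0.62. The aquaporin gene aqp-1 rose by 2.20 on the log2 scale from 22.4 ± 0.731 CPM, and icl-1, which encodes a glyoxylate cycle enzyme, rose 3.95-fold from 26.1 ± 1.76 CPM (wild type mean ± SD, n = 3). The ferritin gene ftn-1 rose 3.91-fold and dod-3 rose 2.81-fold. aqp-1 overlaps F32A5.3. Of 25 insulin-like peptide genes 5 rose and none fell (8 adjusted over the list alone), among them ins-19 and ins-7, which rose 3.14-fold and 2.66-fold, and ins-11, which rose from 1.08 ± 0.308 to 4.56 ± 0.651 CPM (SD, n = 3 each). Of 91 neuropeptide genes 19 rose and none fell (22 adjusted over the list alone), with nlp-66, flp-8, flp-14 and flp-18 rising 2.56-fold, 1.96-fold, 1.91-fold and 1.81-fold. camera gave adjusted p = 1.9e-05 for DAF-16 targets, 0.0037 for insulin-like peptides and 6.4e-07 for neuropeptides, and the adjusted p was 0.089, 0.11 and 0.15 with an estimated correlation.

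Of 49 tested lincRNA genes with a linc name, linc-4 among them, 6 rose and 1, linc-4 itself, fell (6 and 1 adjusted over the list alone). Over all tested genes 1591 of 13778 rose, a share close to that of these lincRNAs. All annotated lincRNAs gave 51 tested genes, of which 7 rose and 1 fell; the further call was lep-5, which rose 2.33-fold and is named here after its value was seen. linc-37 rose 6.72-fold, and linc-15 rose 2.25-fold, from 31.9 ± 6.05 to 71.9 ± 3.49 CPM (SD, n = 3 each), though linc-15 overlaps ucr-2.1. linc-38 had 6 wild type and 55 mutant reads, a ratio of 5.30 with a 95% counting interval of 2.29 to 15.1. linc-34, linc-24 and linc-8 rose 2.29-fold, 1.86-fold and 1.69-fold; the call of linc-34 was lost without wild type 2 (adjusted p = 0.052), and that of linc-24 when any of 4 libraries was left out, with an adjusted p up to 0.13 without wild type 3. camera gave adjusted p = 0.036 for the list and 0.15 with an estimated correlation. The list holds linc-4 itself, whose fall was fixed by the deletion and works against a rise of the list. Its log2 fold changes had a mean of 0.20 and a median of 0.32. Each list result given here, lost calls among them, depends partly on linc-4, and the list was not tested without it. The list call was lost without wild type 2 (adjusted p = 0.26), without any 1 of the linc-4 libraries (0.12 for linc-4 1 and 0.13 for the others), without the low-count filter (0.74) and with upper-quartile scaling (0.070). In a list test on the statistics of the authors' deposited table the adjusted p was 0.40.

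Of 19 tested genes of the DBL-1 pathway, the BMP-like pathway that sets body size in C. elegans, 1 rose and 1 fell (the same counts adjusted over the list alone). sup-17, an ADAM metalloprotease, fell from 46.3 ± 1.64 to 23.6 ± 0.837 CPM (SD, n = 3 each; adjusted p = 0.00089), and sma-10, a transmembrane regulator of the pathway, rose 2.03-fold (adjusted p = 0.033), a call lost when any library other than wild type 2 was left out, with an adjusted p up to 0.15 without wild type 3. The list did not pass camera (adjusted p = 0.59). Of 23 insulin, TOR and DAF-7 growth signalling genes 2 rose, pqm-1 by 1.88-fold and daf-14 from 8.98 to 20.2 CPM, and 1 fell, raga-1 by 1.47-fold, with the same counts adjusted over the list alone and camera adjusted p = 0.22. The calls of daf-14 and raga-1 were each lost without wild type 1, wild type 2, linc-4 1 or linc-4 2, with adjusted p up to 0.11 and 0.15 without linc-4 2. Of 141 cuticle collagen genes 31 rose and 19 fell (35 and 22 adjusted over the list alone; camera adjusted p = 0.13), and the call of the list was gained without wild type 2 (adjusted p = 0.0081) and without the low-count filter (adjusted p = 0.040). Besides col-74 and col-165, dpy-14 fell 2.58-fold and col-95 fell 2.27-fold.

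Somatic tissue markers and stress genes were mixed. Of 31 body wall muscle genes 3 rose, tni-3, unc-27 and mlc-2 (3 adjusted over the list alone). tni-3 overlaps phy-3 and mlc-2 overlaps C36E6.2, so part of their reads may belong to those genes. Without linc-4 2, mlc-2 had adjusted p = 0.053 by limma-voom. The muscle list gave camera adjusted p = 0.086. It passed without wild type 1 (0.035), without linc-4 3 (0.017), without the low-count filter (0.013) and with upper-quartile scaling (0.044). Of 24 neuron genes 1 rose (1 adjusted over the list alone; camera adjusted p = 0.27, fry adjusted p = 0.016 for a rise), and of 33 larval moulting genes 4 rose (2 adjusted over the list alone; adjusted p = 0.27). Of 17 intestine genes 3 rose and 1 fell (3 and 3 adjusted over the list alone): the cathepsin B genes cpr-1 and cpr-4 rose 1.99-fold and 1.86-fold, and erm-1 fell 1.47-fold, a call lost in 4 of 6 fits with 1 library left out (adjusted p up to 0.083, without linc-4 2). Their median was -0.07, their mean 0.03 and camera gave adjusted p = 0.80 for a fall. Of 8 somatic gonad genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), and camera gave adjusted p = 0.25. Of 14 heat shock genes 5 rose and 6 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.69), with hsp-16.2 and hsp-12.3, small heat shock proteins, up 3.95-fold and 3.04-fold and the chaperone gene hsp-110 down 1.67-fold. Of 18 endoplasmic reticulum stress genes 5 fell (5 adjusted over the list alone), with sel-11 and sel-1 falling 1.73-fold and 1.52-fold. The sel-1 call was lost in 2 of 6 fits with 1 library left out (adjusted p up to 0.062, without linc-4 2). For the endoplasmic reticulum stress list camera gave adjusted p = 0.013, or 0.15 with an estimated correlation. Of 11 mitochondrial stress genes 1 fell (1 adjusted over the list alone; camera adjusted p = 0.14, or 0.047 without linc-4 3).

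Metabolic and housekeeping lists completed the comparison. Of 43 fatty acid metabolism genes 9 rose and 4 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.21), with lipl-2, a lipase gene, up 2.46-fold and lbp-7, a lipid binding protein gene, up 1.68-fold beside acs-2 and acdh-1. Of 131 detoxification genes 14 rose and 11 fell (14 and 12 adjusted over the list alone), with a median of -0.06, a mean of 0.05 and camera adjusted p = 0.73; cyp-37B1 rose 4.34-fold and ugt-62 fell 2.05-fold. Of 78 cytosolic ribosomal protein genes 1 rose and 4 fell (1 and 2 adjusted over the list alone), and rps-17 was up 1.65-fold while rla-0, rpl-9 and rpl-1 were down 1.53-fold, 1.51-fold and 1.48-fold. Without linc-4 2 these 4 calls were lost, with adjusted p = 0.097, 0.086, 0.075 and 0.094. The calls of rla-0 and rpl-1 were lost in 2 and 4 of 6 fits with 1 library left out. For the ribosomal protein list the camera adjusted p was 0.024, or 0.73 with an estimated correlation. It was 0.98 without wild type 2, 0.082 without linc-4 1 and 0.060 with upper-quartile scaling. The list did not pass fry (adjusted p = 0.47). Of 35 histone genes 7 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.16), and copies of this family share reads. Of 211 F-box and BATH genes 8 rose and 9 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.27), with fbxa-99 up 5.49-fold. On chromosome V, fbxa-99 lies from 15981691 to 15982854, beside oac-20, which ends at 15981666 and rose 10.2-fold. Whether reads running past the end of oac-20 were counted for fbxa-99 was not tested. Of 12 OXPHOS genes of the mitochondrial genome 2 rose (2 adjusted over the list alone; adjusted p = 0.55). None of 42 nuclear OXPHOS genes passed limma-voom (0 adjusted over the list alone; 6 at an unadjusted p under 0.05; camera adjusted p = 0.69, with a direction that turned with upper-quartile scaling, without the low-count filter and without wild type 2).

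**Figure D3:**
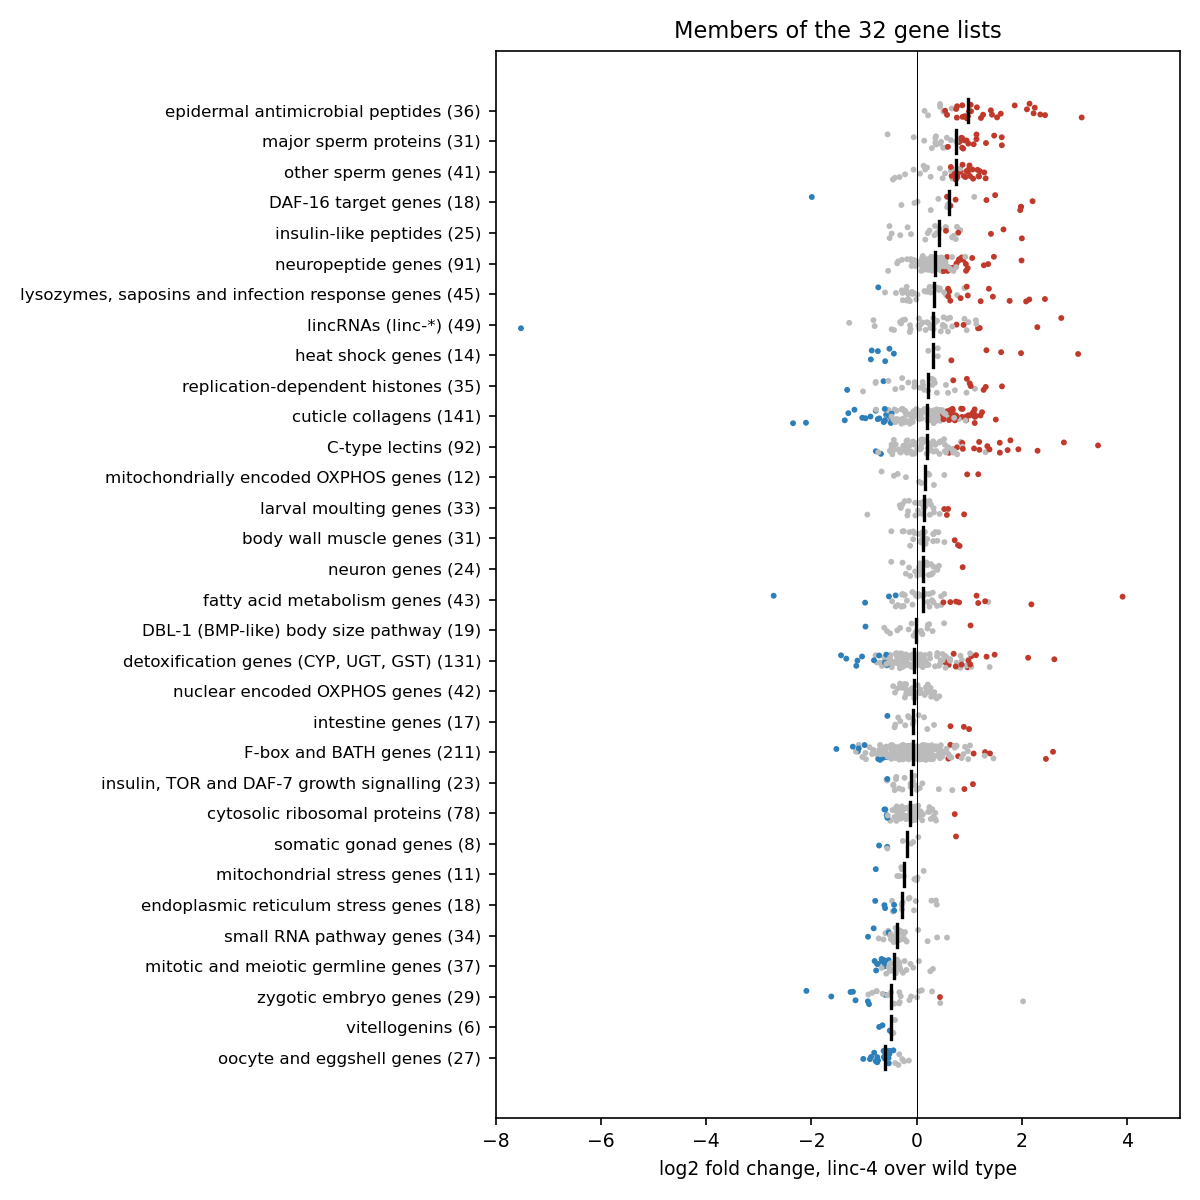
Log2 fold change of linc-4 over wild type (x axis) for each tested member of the 32 gene lists (y axis, number tested in parentheses, ordered by median); red points rose and blue points fell at an adjusted p under 0.05 by limma-voom, grey points did not pass, and black lines are list medians. Epidermal antimicrobial peptides stand highest, with a median of 0.98, and oocyte and eggshell genes lowest, with a median of -0.60.

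Of the 32 lists, 16 passed camera, 9 of them higher and 7 lower. None passed with an estimated correlation, the lowest adjusted p being 0.089, though 10 had an unadjusted p under 0.05. With fry, which asks whether the genes of a list move 1 way on balance, 13 of the 16 passed and 3 did not: major sperm proteins, C-type lectins and cytosolic ribosomal proteins. The neuron list passed fry and not camera.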

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

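Limma-trend and the authors' deposited table were alternatives chosen after seeing the data. The linc-4 transcript was lower with every alternative that tested it, at a log2 fold change from -8.23 to -6.88 when 1 library was left out, and no named gene changed sign. The count of 2580 genes became 1714 with the replicate block, 894 at a log2 fold change of at least 1 and 235 in a test against 0.5. The last settings ask for a larger change. The block leaves fewer degrees of freedom, and other causes of its lower count were not tested. With 1 library left out the count ran from 947 (without linc-4 2) to 2851 (without wild type 2). It was 1136 without wild type 1, 1501 without wild type 3 and 1715 without linc-4 1. Fewer libraries leave fewer degrees of freedom, and the cause of the differences between libraries was not tested. The authors' deposited table called 2018 genes, 1956 of them shared. The 16 lists became 0 with an estimated correlation in camera, with 10 lists at an unadjusted p under 0.05, and the cause was not tested; fry passed 14 lists, of which 13 are among the 16; leaving out 1 library gave 14 to 17 lists and 2 to 3 neighbours. Of the named genes, 29 lost their call without linc-4 2 and 18 with the block. Nothing in the labels says that replicate numbers pair the libraries, and the sample titles also give wild type 1 and wild type 2 other numbers. Deviations of libraries with the same number correlated at 0.097, -0.11 and -0.41, which gave no sign of such a pairing. By contrast, wild type 2 correlated at 0.486 with linc-4 3 and wild type 3 at 0.405 with linc-4 1. On the second principal component wild type 2 (-31.5) and linc-4 3 (-15.8) stood apart from the other libraries. The lincRNA list lost its call with the block (adjusted p = 0.066). With upper-quartile scaling 8 named genes lost their call and 1 gained it, and 8 lost it without the filter; among those lost with each were raga-1, sid-1, vit-1 and vit-2. A new DESeq2 fit was not run. The edgeR test was run once before limma-voom was chosen, and its values are not used here; other pseudocounts do not apply to limma-voom. Depth limits low genes most in wild type 1, where 3 reads make 0.771 CPM.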

Other observations

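The ontology terms and all tests below, apart from the splits of the libraries, were chosen after the results were seen. Among genes lower in linc-4, cell cycle genes were 53 of 165 against 13.1 by chance (adjusted p = 2.4e-16, hypergeometric test), P granule genes 31 of 67 and oogenesis genes 23 of 48. Among genes higher in linc-4, the term for innate immune response held 50 of 202 (adjusted p = 2.0e-09), that for defence against other organisms 13 of 18, that for neuropeptide signalling 27 of 108 and that for structural constituents of the cuticle 32 of 139. The cuticle collagen list moved both ways, with 31 higher and 19 lower (camera adjusted p = 0.13). The pseudopodium term, a structure of crawling sperm, held 16 of 37, and serine phosphorylation of peptides 26 of 113. Of 1026 terms, 15 passed for higher and 102 for lower genes; the test treats genes as independent.

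Of the nuclear chromosomes, V had the largest share of higher genes, 15.4% of 2668 tested, and X had the smallest share of lower genes, 3.09% of 1843. Of 277 tested pseudogenes 23 were higher and 11 lower.

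The 10 splits of 3 against 3 are too few for a share under 0.05. The real split, 1 of 10, gave 2580 genes, and the highest of the others gave 0. For lists, 2 of 10 splits gave as many as the real one: it gave 16, and wild type 1, wild type 3 and linc-4 2 against the rest also gave 16. Each other split still parts 4 of the 6 libraries by genotype and mixes the genotypes within both groups. That mixing widens the spread within groups, so the 0 calls of the other splits do not measure chance. The number of lists from camera with a preset correlation does not set the real split apart either, since another split also gave 16.

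Sperm lists were higher and oocyte lists lower in linc-4, and within each group the mean log2 CPM of sperm genes was highest in wild type 2 (4.40) and in linc-4 3 (4.93). Scaling moves all genes of a library alike and would leave the difference between sperm and oocyte lists nearly unchanged. That difference moved by 1.21 on the log2 scale (SE 0.149), with no overlap between groups. The exact permutation p was 0.1 (two-sided), the smallest that 3 against 3 allow. The moved difference restates the pattern and is no separate test, but scaling alone is argued against. A lower share of oocytes alone would raise sperm and somatic (muscle and neuron) genes alike. Their difference moved by 0.484 (SE 0.228, exact permutation p = 0.2) with wild type 2 inside the mutant range, so this cannot be told apart from a change in sperm genes. An earlier adult stage at harvest stays open too. The larval moulting list gave camera adjusted p = 0.27, but its genes concern larval moults, so it cannot tell younger adults from older ones. The vitellogenin and zygotic embryo lists, also lower in linc-4, were not tested as markers of adult age. A direct effect of the linc-4 deletion also stays open and was not tested.

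F13H8.8 was 15.2-fold higher beside the deleted gene. Reads of an annotated overlapping gene are argued against, since 0 annotated genes overlap it. Transcripts outside the annotation were not tested, and the extent of the deletion is not given. A change shared by the neighbourhood on both sides is also argued against: the other 9 neighbours had a median absolute log2 fold change of 0.22, at percentile 16.16 of 13722 runs of 9 genes. Of the other 4 neighbours on the side of F13H8.8, F13H8.12 and nmgp-1 were called higher, while F13H8.3, between them and F13H8.8, had a log2 fold change of -0.41 (SE 0.19, adjusted p = 0.14 by limma-voom over all genes) and F13H8.11 of 0.12 (SE 0.49, adjusted p = 0.88), so a change of some genes on that side stays open. An effect of the linc-4 deletion, the genotype of the design, also stays open and was not tested.

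The genes at least 8-fold higher in linc-4 with a mean count of at least 50 numbered 13, and 8 of them lie on chromosome V, which holds 19.4% of tested genes. The prediction for a linked block of genes, written after these genes were seen, was met. Within 500 kb of chromosome V start 4 of the genes, acs-2, haf-3, F57A10.4 and oac-20. Of 10000 random draws from the tested genes, 0.07% held as many in such a window. The draws did not keep 8 genes on V, so the low share may partly restate the excess there and is no separate support for a block. The draws place genes independently, while haf-3 ends at 15766172 and F57A10.4 starts at 15769438. Neighbouring genes that change together could therefore also give a low share, and the test cannot tell them from a linked block. Of the other 9 genes, drd-50 and F49F1.7 also lie near each other, starting at 4117732 and 4123525 on chromosome IV, which linkage to the block on V does not cover. A variant of the mutant line linked to that block, away from linc-4 on chromosome II, may account for the 4 genes there, as may shared regulation, and the libraries cannot separate either from the linc-4 genotype.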
